A study of Homo sapiens with 6 samples.

How the data were processed

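The series holds 6 RNA-seq libraries from RPE1 cells, 3 given 2.5 µM Nutlin-3 and 3 given DMSO, for 24 h. Per the labels' protocols, poly(A) RNA was made into stranded libraries with a TruSeq Stranded mRNA kit. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2, edgeR and the genome build hg19 were used, without a stated role for each. The counter, the gene annotation and whether counting used strand are not given in the sources used here. The deposited table gives RPKM, made by the authors, with 1 column per library. The name of each column matched 1 library title, and 0 columns were left unmapped. Groups and replicate numbers were taken from the labels. The labels describe triplicates but do not say whether these came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

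The unit was examined on low values. Where whole reads are counted, RPKM times gene length is a whole multiple of a fixed step in each library. Using the span of each gene in GENCODE 29, introns included, 89.2% of low values were whole within 0.01 of a read, against 31.3% with the merged exon length. The deposited RPKM were thus made with the whole gene span, and a long gene has a low RPKM even with many reads. Spans from GENCODE 29 gave whole reads for 27538 genes, and for 8825 others the smallest whole numbers with the ratios found between libraries were taken. These may be too low by a whole factor, and tests on reads use them. Another 21410 genes were at 0 in every library. The library sizes behind the RPKM were 42.3, 29.8 and 32.4 M in DMSO replicates 1 to 3 and 31.6, 35.8 and 30.4 M in Nutlin-3 replicates 1 to 3. They were 1.03, 1.05 and 1.04 times the recovered reads in DMSO and 0.983, 0.971 and 0.964 times in Nutlin-3, so the authors' library sizes were scaled, not raw totals. With these sizes, 1 read in a gene of 10 kb equals between 0.00237 and 0.00336 RPKM.

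Replicates were compared before averaging. Over genes with at least 20 reads per pair of libraries, the chi-square per gene was between 1.67 and 4.83 within groups and between 54.8 and 80.7 across groups, so no pair of replicates agreed within sampling noise and each library was counted as 1 replicate.

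The main test, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Genes with a mean of at least 0.5 RPKM over the 6 libraries were tested on log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, group as the only term) and Benjamini-Hochberg adjustment. Fold changes on this scale understate the change of low genes, and folds and percentages of the DMSO level in the text are ratios of mean RPKM. Gene lists with at least 5 tested members were tested with limma's camera, which compares a list with the other genes, using a preset correlation of 0.01, and again with a correlation estimated per list. limma's fry, which tests whether the genes of a list move on balance one way, was run as an alternative. It does not compare a list with the other genes. As 51.6% of tested genes changed, a fry call says little about a list against the rest. G2/M and G1/S lists were compared by the difference of their mean log2 values per library, with a 2-sided exact permutation test. The filter was planned for RPKM made with exon length. Because the span was used instead, it left out many long genes, and limma voom was run on the recovered reads as an alternative, on genes with a mean of at least 10 reads and with the authors' library sizes. As the deposited unit is RPKM, it is not the main test.

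Named genes are, by rule, the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 1 RPKM and no overlap between the groups, and the members of each list with the largest changes past the threshold (the rule says a list with a call, read as a list with at least 1 member past the threshold), up to 3 for p53, G1/S and G2/M lists and up to 2 for others. Up to 2 members that moved against their list, the highest member of each p53 target list that did not pass, and MDM2, CDKN1A, MDM4, GAPDH and ACTB in any case were added. Some genes that this rule takes are not reported here, and no others took their place. Other names are marked as chosen after their values were seen. Symbols came from GENCODE 29 and a table of gene names, which gave one for 52338 of the 57773 IDs. Of 830 members of 30 lists, 817 matched an ID. GENCODE 29 uses another build than the deposited table, so no coordinates are given, and it served only for names, lengths and the overlap of genes. On the same strand, PHLDA3 shares 19.1%, SERPINB2 19.9% and TRIM22 10.7% of the exon length with other genes. Over 148 pairs of genes in which one lies wholly in exons of the other on the same strand, the log2 fold changes on reads of both genes correlated across pairs with a Spearman rho of 0.489. Over 53 such pairs on opposite strands rho was 0.0273. Pairs of genes are not independent replicates.

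The tests were first run on simulated reads drawn from the real means and library sizes, with a coefficient of variation of 2.05% beyond counting noise and 200 genes changed. limma on log2(RPKM + 0.5) recovered 44.1% of the tested changed genes at 1.25-fold, 76.1% at 1.5-fold and 89.2% at 2-fold, with between 5 and 13 false calls over 12191 to 12219 genes. limma voom recovered 76.4%, 88.0% and 98.4%. Every simulated gene had the same spread and was drawn independently. These rates need not hold for genes with a wider spread or for lists whose genes move together. Only 200 genes were changed, against 51.6% of tested genes in the real data. The Benjamini-Hochberg cut-off depends on that share, so the rates may differ for the real data. camera found the 1 list of raised genes and called 0 of 20 random lists of 40 genes. On the real data it also called lists in splits of the libraries that mix the groups. Such splits keep part of the treatment difference, so these calls do not measure false calls. How often camera calls falsely on these data was not measured, so a camera call alone stays weak evidence.

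Alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 1 RPKM, median-of-ratios scaling, quantile normalization, eBayes without trend and with robust variances, the replicate number as a block, each library left out in turn, limma voom on the reads, an estimated correlation, fry, and lists without shared members. Chosen after the data were seen were the fit without genes under 300 bases, and the use of the recovered reads for changes of at least 2-fold, lists, named genes and the cell cycle parts. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.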

Results

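RPE1 is an immortalised line of human retinal pigment epithelial cells. Nutlin-3 is a small molecule that occupies the p53-binding pocket of MDM2, the ubiquitin ligase that keeps the transcription factor p53 low, and DMSO is its solvent. The series asks which genes respond to p53 in these cells. Its comparison sets 3 libraries from cells given 2.5 µM Nutlin-3 for 24 h against 3 libraries from cells given DMSO. Poly(A) RNA was sequenced from strand-specific libraries, and the deposited table holds RPKM for 57773 Ensembl gene IDs, of which 36363 were above 0 in at least 1 library. The reads recovered from these RPKM came to 40.9, 28.3 and 31.3 M in DMSO replicates 1, 2 and 3 and to 32.1, 36.9 and 31.5 M in Nutlin-3 replicates 1, 2 and 3. The first principal component of the tested genes held 65.3% of the variance and separated the groups, with the DMSO libraries between -20.7 and -17.5 and the Nutlin-3 libraries between 18.9 and 19.3.

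With Nutlin-3, CDKN1A (ENSG00000124762), which encodes the cyclin-dependent kinase inhibitor p21, rose from 8.36 ± 0.463 to 60.5 ± 2.34 RPKM (mean ± SD, n = 3 per group), 7.24 times its DMSO level. MDM2 (ENSG00000135679), the protein target of the drug and itself a p53 target gene, rose from 2.31 ± 0.0866 to 8.46 ± 0.225 RPKM, 3.66 times its DMSO level. MKI67 (ENSG00000148773), the proliferation marker Ki-67, fell from 27.3 ± 0.817 to 7.45 ± 0.356 RPKM, and RRM2 (ENSG00000171848), a subunit of ribonucleotide reductase, fell from 28.4 ± 2.24 to 8.05 ± 0.449 RPKM. On the log2(RPKM + 0.5) scale the changes were 2.78 (SE 0.051, adjusted p = 2.36e-05 by limma) for CDKN1A, 1.67 (SE 0.035, adjusted p = 2.91e-05) for MDM2, -1.81 (adjusted p = 3.59e-05) for MKI67 and -1.76 (adjusted p = 5.61e-05) for RRM2. MDM4, the MDM2 relative that also restrains p53, fell slightly, from 0.709 ± 0.0351 to 0.627 ± 0.0160 RPKM (adjusted p = 0.0405). That call was lost when any 1 of 5 libraries was left out, all but DMSO replicate 3, with adjusted p from 0.0734 to 0.123, without a filter (adjusted p = 0.0777) and under quantile normalization (adjusted p = 0.0996). On the recovered reads the fall passed (-0.18, limma voom adjusted p = 3.38e-03).

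Of 12212 genes tested, 6296 changed at an adjusted p under 0.05, 3551 upwards and 2745 downwards. Under median-of-ratios scaling the counts were even, with 3206 upwards and 3216 downwards. Changes of at least 2-fold were fewer and leaned downwards, with 55 genes that rose and 212 that fell. The size of that second count followed the pseudocount, from 434 genes at 0.1 to 152 at 1. The RPKM were made with the whole gene span, introns included, so that long genes have low RPKM for their reads. Genes tested on the recovered reads alone had a median span of 44396.5 bases, against 12978.5 bases for genes tested both ways. limma voom on the recovered reads tested 20732 genes and called 10425, of which 994 changed at least 2-fold.

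**Figure D1:**
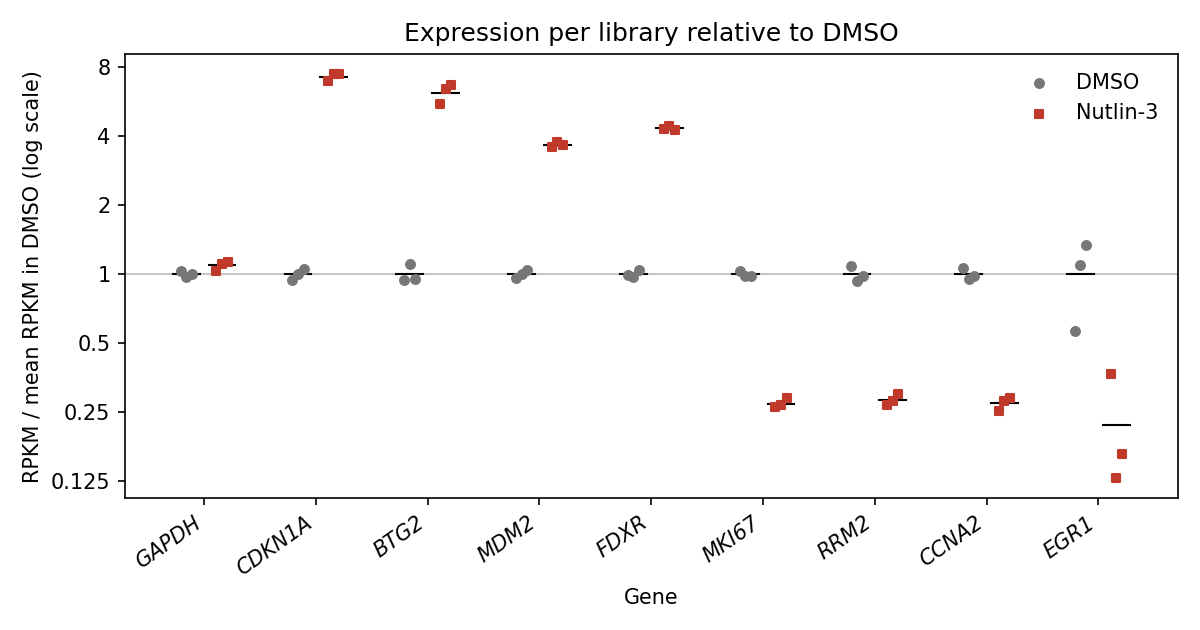
RPKM of 9 genes in each of the 6 libraries, divided by the gene's mean RPKM in DMSO, on a log axis. Grey circles are the 3 DMSO libraries, red squares the 3 Nutlin-3 libraries and black bars the group means. CDKN1A lies between 6.92 and 7.41 times its DMSO mean in the Nutlin-3 libraries and MKI67 between 0.263 and 0.288.

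Among genes with a mean RPKM of at least 1 and no overlap between the groups, the 6 with the largest rise on log2(RPKM + 0.5) were CDKN1A, BTG2, MIR3687-2, AC025423.2, FDXR and MDM2. BTG2, an antiproliferative p53 target, rose from 0.845 ± 0.0811 to 5.21 ± 0.519 RPKM, and FDXR, the mitochondrial ferredoxin reductase, from 1.01 ± 0.0375 to 4.34 ± 0.0858 RPKM. AC025423.2 is a processed pseudogene whose exon lies wholly inside exons of MDM2 on the same strand, so its rise of 1.83 cannot be separated from that of MDM2. The microRNA gene MIR3687-2 rests on 2 to 19 reads per library and is uncertain. The 6 genes with the largest fall on that scale were a Y RNA gene (ENSG00000222881), the 7SL pseudogene RN7SL396P, 3 IDs without a symbol in the tables used here (among them ENSG00000265150 and ENSG00000258486), and EGR1. The Y RNA gene rests on 0 to 31 reads per library and is uncertain too. EGR1, an immediate early transcription factor induced by growth factors, fell from 13.4 ± 5.28 to 2.95 ± 1.72 RPKM (adjusted p = 0.0130), with a wide spread inside both groups. RN7SL396P fell from 9.55 ± 4.52 to 1.94 ± 1.29 RPKM (adjusted p = 0.0152). Its call was lost without Nutlin-3 replicate 2 (adjusted p = 0.0501), and 7SL copies are near-identical, so reads may be split between them.

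Genes of the p53 response rose together in 6 lists of known p53 targets and regulators. Of the 14 tested genes of the cell cycle arrest list, 13 rose and 1 fell, with a median log2 fold change of 0.72 (camera adjusted p = 4.56e-06, adjusted p = 0.172 with an estimated correlation). Besides CDKN1A and BTG2 it held ZMAT3, an RNA-binding protein, which rose from 1.22 ± 0.0962 to 4.73 ± 0.110 RPKM. The member that fell was E2F7, an E2F family repressor, from 1.73 ± 0.0640 to 1.06 ± 0.0372 RPKM. In the apoptosis list 11 of 14 rose and 1 fell, with a median of 0.81 (camera adjusted p = 4.44e-05, adjusted p = 0.138 with an estimated correlation). EDA2R, a receptor of the TNF receptor family, rose 3.94-fold, BBC3, which encodes PUMA, 3.82-fold and the death receptor gene FAS 2.58-fold. PMAIP1, which encodes the BH3-only protein NOXA, fell from 3.93 ± 0.263 to 2.66 ± 0.215 RPKM. PIDD1 did not pass (log2 fold change -0.054, adjusted p = 0.333).

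In the list of p53 regulators 6 of 7 genes rose and MDM4 fell, with a median of 0.89 (camera adjusted p = 1.60e-03, adjusted p = 0.172 with an estimated correlation). TP53INP1, a stress-induced p53 cofactor, rose from 1.62 ± 0.113 to 5.42 ± 0.141 RPKM and PHLDA3, an inhibitor of AKT, rose 1.94-fold. In the list of DNA repair and nucleotide supply 6 of 8 rose and 1 fell, with a median of 0.45 (camera adjusted p = 4.75e-03, adjusted p = 0.172 with an estimated correlation). TRIM22 rose 3.80-fold, the ribonucleotide reductase subunit RRM2B 2.40-fold and RPS27L 1.88-fold. PCNA, the sliding clamp of DNA polymerases, fell from 14.6 ± 0.998 to 8.46 ± 0.217 RPKM. REV3L, the catalytic subunit of polymerase zeta, did not pass on RPKM (log2 fold change 0.097, adjusted p = 0.0892) and rose on the recovered reads (0.19, limma voom adjusted p = 1.61e-03).

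All 16 tested genes of the metabolism and autophagy list rose, with a median of 0.42 (camera adjusted p = 4.10e-07, adjusted p = 0.172 with an estimated correlation). Among them FDXR rose 4.30-fold, TIGAR, a fructose bisphosphatase, 2.69-fold and SESN2, a leucine sensor upstream of mTORC1, 2.45-fold. All 12 tested genes of the list of secreted and surface proteins also rose, with a median of 0.56 (camera adjusted p = 2.05e-06, adjusted p = 0.115 with an estimated correlation). Among them the insulin-like growth factor binding proteins IGFBP7 and IGFBP3 rose 1.84-fold and 1.81-fold. Of the p53-regulated long noncoding RNAs, NEAT1, the scaffold of paraspeckles, was the 1 gene tested, and rose from 56.0 ± 2.17 to 70.5 ± 3.90 RPKM. Quantile normalization ended its call (adjusted p = 0.0684). Adjusted over the list alone, the counts were the same as over all genes in these lists and in every list below for which no other count is given.

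Every tested gene of the 4 cell cycle lists fell. These were 41 E2F targets of G1/S, 58 genes of G2/M and mitosis, 32 genes of the kinetochore and condensin, and 17 genes of homologous recombination and Fanconi repair. The median log2 fold changes were -1.01, -1.27, -0.97 and -1.13. The camera adjusted p-values were 7.84e-24, 6.40e-33, 1.06e-20 and 2.45e-11, and with an estimated correlation they were adjusted p = 0.186, 0.172, 0.172 and 0.172. The estimated correlations were 0.797, 0.762, 0.662 and 0.596. Genes of these lists thus moved together far more than the preset of 0.01 assumes. In G1/S, cyclin A2 (CCNA2) fell from 15.1 ± 0.903 to 4.15 ± 0.291 RPKM and MCM7, a subunit of the replicative helicase, from 24.4 ± 1.57 to 8.30 ± 0.457 RPKM. In mitosis, the kinesin KIF20A fell to 29.6% and CDC20, an activator of the anaphase-promoting complex, to 30.9% of the DMSO level. The centromeric histone chaperone HJURP fell to 27.6%, ZWINT of the outer kinetochore to 33.5%, the recombination factor PSMC3IP to 30.8% and the Fanconi ubiquitin-conjugating enzyme UBE2T to 31.8%. PSMC3IP shares 29.9% of its exon length with MLX on the opposite strand.

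**Figure D2:**
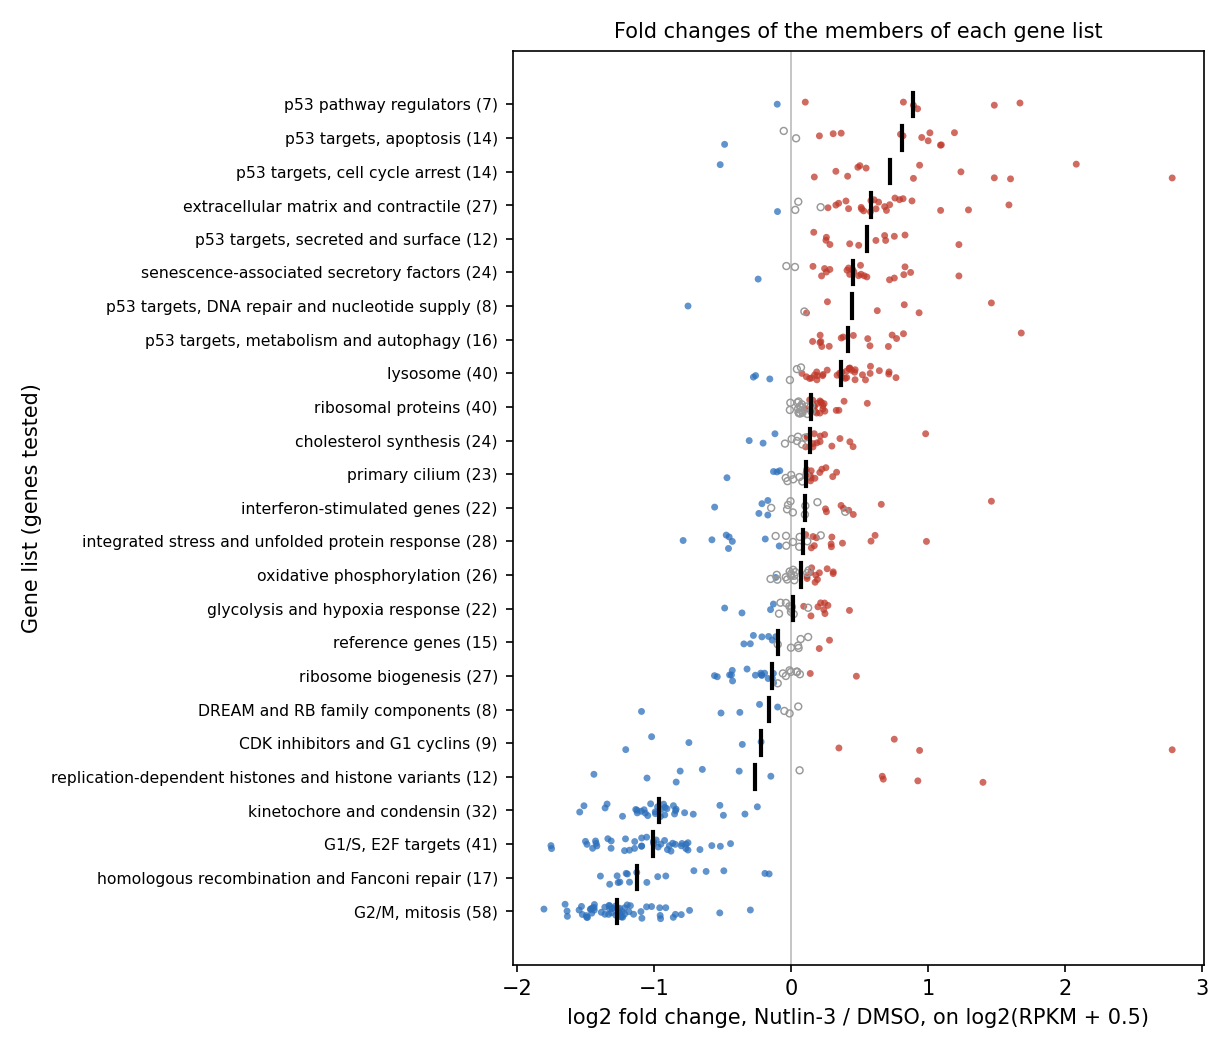
Log2 fold change (Nutlin-3 over DMSO, on log2(RPKM + 0.5)) of every tested member of each gene list with at least 5 tested genes, ordered by the median, which is the black bar. Red points rose and blue points fell at an adjusted p under 0.05, open grey points did not pass, and the number tested stands in brackets. All 58 G2/M genes and all 41 G1/S genes lie left of 0.

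A further question was whether both parts of the cell cycle programme moved by the same amount. The 58 G2/M genes changed by a mean of -1.25 and the 41 G1/S genes by -1.06. The G2/M mean minus the G1/S mean was 0.388 ± 0.0118 in DMSO and 0.201 ± 0.00736 in Nutlin-3 libraries (log2 scale, n = 3), a difference of -0.19. The 2-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. On the recovered reads, over 62 and 54 genes, the means were -1.58 and -1.47 and the difference was -0.12. The size of the difference thus depends on the unit and the filter.

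Histone genes split into opposite directions. Of 12 tested, 7 fell and 4 rose, and the list as a whole did not pass (camera adjusted p = 0.197), while fry called it downwards (adjusted p = 0.0101). The genes that fell encode histone variants and linker histones outside the main clusters, such as H2AZ1, which fell from 157.0 ± 10.0 to 57.4 ± 1.86 RPKM, and H2AX, which fell to 47.7% of its DMSO level. The 4 that rose, H2BC21, H2AC6, H2BC12 and H1-2, lie in the clusters of replication-dependent histone genes, whose main transcripts lack a poly(A) tail. H2BC21 rose from 0.941 ± 0.202 to 3.29 ± 0.243 RPKM and H2AC6 from 0.311 ± 0.0372 to 1.04 ± 0.0464 RPKM.

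Of 8 tested components of the DREAM complex and the RB family, 5 fell and none rose, with a median of -0.16 (camera adjusted p = 6.27e-03, adjusted p = 0.172 with an estimated correlation). MYBL2, the B-Myb factor of the activating form of the complex, fell to 26.2% of its DMSO level, and TFDP1, the dimerisation partner of E2F factors, to 65.5%. The list's call was lost with a minimum mean of 1 RPKM (adjusted p = 0.119). CDK inhibitors and G1 cyclins went both ways, with 4 of 9 rising and 5 falling. The list did not pass (camera adjusted p = 0.595), its median of -0.22 and mean of 0.14 differ in sign, and fry, which weighs the genes of a list on their own, called it upwards (adjusted p = 0.0293). Besides CDKN1A, cyclin D1 (CCND1) rose from 37.5 ± 1.99 to 72.3 ± 3.33 RPKM, while the kinase gene CDK2 fell from 9.80 ± 0.706 to 3.95 ± 0.0610 RPKM.

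Genes for secreted factors, matrix and lysosomes rose. Of 24 tested genes of the senescence-associated secretory list, 21 rose and 1 fell, with a median of 0.45 (camera adjusted p = 4.10e-07, adjusted p = 0.115 with an estimated correlation). IGFBP3, IGFBP7 and LIF stand in this list and in that of secreted p53 targets. IGFBP5 rose 2.69-fold, and SERPINB2, the plasminogen activator inhibitor PAI-2, fell from 0.658 ± 0.0720 to 0.479 ± 0.0183 RPKM. Of 27 matrix and contractile genes, 23 rose and 1 fell, with a median of 0.58 (camera adjusted p = 1.25e-09, adjusted p = 0.186 with an estimated correlation). Smooth muscle actin (ACTA2) rose from 0.575 ± 0.0942 to 2.73 ± 0.128 RPKM and the myosin light chain MYL9 rose 2.49-fold. ACTA2 shares 30.1% of its exon length with FAS and an antisense RNA on the opposite strand. Tenascin C (TNC) fell to 90.6% of its DMSO level, a call lost without any 1 of DMSO replicates 1 and 2 and Nutlin-3 replicates 1 and 2 (adjusted p from 0.0673 to 0.081).

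Of 40 lysosomal genes, 34 rose and 3 fell, with a median of 0.37 (camera adjusted p = 1.18e-08, adjusted p = 0.172 with an estimated correlation). The peptidase TPP1 rose 1.71-fold and the fucosidase FUCA1 2.00-fold, while the glycosidases GUSB and GLA fell to 78.7% and 79.3% of their DMSO levels. In the cholesterol synthesis list 15 of 24 rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 6.27e-03, adjusted p = 0.455 with an estimated correlation). The sterol reductase TM7SF2 rose 2.09-fold and the sterol oxidase MSMO1 1.38-fold. EBP, the sterol isomerase, fell from 8.05 ± 0.210 to 6.42 ± 0.352 RPKM. PMVK, phosphomevalonate kinase, fell to 82.1% of its DMSO level, a call lost without any 1 of DMSO replicates 1 and 3 and Nutlin-3 replicates 2 and 3 (adjusted p from 0.0589 to 0.0657) and without a filter (adjusted p = 0.0527). Quantile normalization ended the list's call (adjusted p = 0.0584).

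Several stress and metabolic lists did not pass as sets, although members moved. Of 28 genes of the integrated stress and unfolded protein response, 12 rose and 8 fell (12 and 9 adjusted over the list alone; camera adjusted p = 0.637). PHGDH and PSAT1, which act in sequence in serine synthesis, fell to 40.1% and 59.7% of their DMSO levels, and asparagine synthetase (ASNS), MTHFD2 and SHMT2 fell too. DDIT4, an inhibitor of mTORC1, rose from 17.1 ± 2.03 to 34.3 ± 3.10 RPKM, and the chaperone genes HSPA5 and DNAJB9 rose 1.23-fold and 1.65-fold. Of 22 glycolysis and hypoxia genes, 9 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.589). The glucose transporter SLC2A1 rose 1.35-fold, and the enolases ENO1 and ENO2 fell to 77.9% and 70.2%. The set direction of both lists turned under quantile normalization, without a call (adjusted p = 0.908 and 0.670). ASNS, MTHFD2, SHMT2, HSPA5, DNAJB9, H2AX, H2BC12, H1-2, RDH5 and LIF were named after their values were seen.

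Of 26 oxidative phosphorylation genes, 11 rose and 1 fell (camera adjusted p = 0.136, and 6.4e-03 without a filter). NDUFA4 rose 1.25-fold and COX5B 1.24-fold, and SDHA fell to 91.0% of its DMSO level, a call lost without any 1 of DMSO replicate 2 and Nutlin-3 replicates 1 and 2 (adjusted p from 0.0607 to 0.0735). Of 22 interferon-stimulated genes, 8 rose and 5 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.197). The largest rise in it was that of TRIM22, which is also in the p53 lists, followed by ISG15, a ubiquitin-like modifier, at 1.66-fold. OAS3 fell to 53.8% and DTX3L to 83.0% of their DMSO levels. Of 23 genes of the primary cilium, 12 rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.0977). BBS1 of the BBSome rose 1.42-fold but shares 53.9% of its exon length with another gene on the same strand. ODF2, a centriolar appendage protein, fell to 63.9%, and the small GTPase ARL3 to 88.6%. The cilium list passed under quantile normalization (adjusted p = 0.0343), and the interferon list with a minimum mean of 1 RPKM (adjusted p = 0.0425). On the recovered reads 13 of 35 interferon-stimulated genes rose and 10 fell, and that list did not pass (camera adjusted p = 0.335). fry called the cilium, interferon and oxidative phosphorylation lists upwards (adjusted p = 2.55e-05, 1.31e-03 and 0.0386).

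Of 40 ribosomal protein genes, 23 rose and none fell, with a median of 0.15 (camera adjusted p = 4.26e-05, adjusted p = 0.552 with an estimated correlation). RPS19 rose from 26.3 ± 0.627 to 38.9 ± 0.602 RPKM and RPL13 from 92.7 ± 5.38 to 121.3 ± 5.68 RPKM. Quantile normalization ended the list's call (adjusted p = 0.252) and left 12 genes that rose and 5 that fell. Of 27 ribosome biogenesis genes, 16 fell and 2 rose, with a median of -0.14 (camera adjusted p = 1.04e-03, adjusted p = 0.552 with an estimated correlation). The box C/D nucleolar proteins NOP56 and FBL fell to 67.0% and 66.8% of their DMSO levels, and RRS1 and RRP12 rose 1.40-fold and 1.15-fold. Under quantile normalization and under median-of-ratios scaling 17 fell and 2 rose.

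Of 15 genes often used as references, 7 fell and 2 rose (7 and 3 adjusted over the list alone), and the list passed only under quantile normalization (camera adjusted p = 0.197, and 8.32e-04 under it). HPRT1 fell from 0.753 ± 0.0368 to 0.486 ± 0.00538 RPKM. ACTB rose 1.22-fold, but did not pass under quantile normalization (adjusted p = 0.260). GAPDH stood at 741.4 ± 21.5 RPKM in DMSO and 808.6 ± 36.5 RPKM in Nutlin-3 (adjusted p = 0.0507). Its rise passed under median-of-ratios scaling (adjusted p = 0.0416), without Nutlin-3 replicate 1 (adjusted p = 0.0191) and on the recovered reads (limma voom adjusted p = 3.06e-03), and turned to -0.045 under quantile normalization.

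Of 17 markers of retinal pigment epithelium, 4 were tested on RPKM. On the recovered reads 10 were tested, of which 3 rose, 2 fell and 5 did not pass. The keratin genes KRT18 and KRT8 rose 1.74-fold and 1.68-fold and the retinol dehydrogenase RDH5 rose 1.58-fold, while OTX2, a transcription factor of the retinal pigment epithelium, fell from 3.18 ± 0.240 to 2.60 ± 0.174 RPKM. The OTX2 call was lost without any 1 of DMSO replicates 1 and 2 and Nutlin-3 replicates 1 and 3 (adjusted p from 0.0701 to 0.0719) and without a filter (adjusted p = 0.0616). Most markers of other cell types did not reach the filter. Of 12 blood markers, CD68, a lysosomal membrane protein, was the 1 gene tested and rose from 20.9 ± 0.171 to 25.7 ± 1.36 RPKM, and 81.7% of its exon length lies in another gene on the same strand. None of 10 epithelial and keratinocyte markers reached the filter, and the highest group mean among them was 0.0457 RPKM. Of 11 matched endothelial, muscle and neural markers, the tubulin gene TUBB3 was the 1 tested and fell from 10.8 ± 0.396 to 9.10 ± 0.176 RPKM, and 35.8% of its exon length lies in another gene on the same strand. As RPKM were made with the gene span, a low value does not show that a marker was silent. On the recovered reads 3 blood, 2 epithelial and keratinocyte, and 2 endothelial, muscle and neural markers were tested.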

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

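Chosen after the data were seen were the fit without genes under 300 bases and, except for the count of genes changed, the use of the recovered reads. Under the other settings the count of genes changed lay between 4886 with a minimum of 1 RPKM and 7726 with no filter, against 6296, and between 5088 and 5560 when 1 library was left out. limma voom on the recovered reads called 10425 genes, of which 3632 are among 9156 genes that the RPKM filter leaves out. Of 11576 genes tested both ways, 6019 were called both ways, all in the same direction. Genes changed at least 2-fold numbered 434 with a pseudocount of 0.1 and 152 with a pseudocount of 1, against 267, as a pseudocount shrinks folds of low genes. On the reads they numbered 994, of which 531 are among the genes that the RPKM filter leaves out. With 1 library left out they numbered between 252 and 283, and without genes under 300 bases 217. With a correlation estimated per list, 0 of the 17 called lists passed, while fry, which sets no list against the other genes, called all 17. The size of the correlation does not account for every lost call. The list of secreted and surface p53 targets had an estimate of 0.0078, below the preset 0.01, and still lost its call (adjusted p = 0.115 by camera). The difference between G2/M and G1/S lay between -0.28 with no filter and -0.12 on the reads, with an exact permutation p = 0.1 throughout.

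Lists that reversed were not called in the main test. They were glycolysis and hypoxia (adjusted p = 0.852 without a filter and 0.670 with quantile normalization), the integrated stress response (0.908 with quantile normalization and 0.998 with fry), and CDK inhibitors and G1 cyclins, called upwards by fry (0.0293). GAPDH (-0.0449) reversed under quantile normalization, which also ended the ACTB, NEAT1 and MDM4 calls. The cause was not tested. In all, named genes kept direction and side of the threshold in 1489 tests of settings, lost the call in 31, gained it in 6 and reversed in 1. The falls of TNC, SDHA, PMVK and OTX2, lost under some settings, passed on the recovered reads. Their limma voom adjusted p-values were 2.22e-03, 3.95e-03, 8.43e-04 and 3.21e-04.

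The labels do not say whether the replicate numbers pair the libraries, and the values showed no clear pairing. Deviations of same-numbered libraries from their group means correlated at -0.025, 0.0079 and 0.017, and not every library correlated best with its own number. With 3 libraries per group, such correlations cannot exclude a pairing. With the number as a block, 5135 genes were called and 267 changed at least 2-fold, all 17 lists and the G2/M difference of -0.19 were as before, and EGR1 (adjusted p = 0.0527), MDM4, TNC and SDHA did not pass. Simulations used the depth of these libraries, the same spread for every gene and 200 changed genes. In them, 44.1% of 1.25-fold changes were recovered on RPKM and 76.4% on reads. As 51.6% of the real tested genes changed, real rates may differ. Depth was not varied.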

Other observations

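The tests of the short RNA genes, of the MDM2 pseudogene, of the authors' scaling and of the pseudocount were chosen only after the results were seen, as were the genes named in the first 3 paragraphs. The recovered reads show p53 targets whose long spans kept them out of the test on RPKM. All values in these paragraphs are from limma voom on the reads. PTCHD4, a membrane protein of the Patched family, rose 7.82-fold (log2 fold change 2.97, SE 0.097, adjusted p = 1.36e-17), from 118.7 to 867.3 reads per library. SPATA18, a mitochondrial quality control factor, rose 6.15-fold, the ceramidase ACER2 3.55-fold, SESN1 2.85-fold and the autophagy regulator DRAM1 2.21-fold. With these, 24 of 25 metabolism and autophagy targets and 18 of 21 secreted and surface targets rose on the reads, and 1 of each list fell. In the list of p53 regulators 9 of 11 rose and 2 fell, in that of DNA repair and nucleotide supply 9 of 13 rose and 4 fell, in that of apoptosis 14 of 18 rose and 2 fell, and in that of cell cycle arrest 13 of 16 rose and 1 fell. GLS2, the mitochondrial glutaminase, rose 3.47-fold but rests on as few as 7 reads. Of 5 long noncoding RNAs tested, TP53TG1 (2.35-fold), PURPL (2.72-fold), PVT1 (1.16-fold) and NEAT1 rose and LINC-PINT fell by 0.41 on the log2 scale. GDF15, a secreted p53 target, had between 6.00 and 9.33 reads per library on average and was not tested.

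The same reads extend the fall of homologous recombination and Fanconi repair genes. All 33 genes of homologous recombination and Fanconi repair fell, among them BRCA2 (-1.79), POLQ (-1.81), EXO1 (-1.99) and FANCD2 (-1.67), as did all 54 G1/S genes, with E2F8 at -2.35 and E2F2 at -2.08. FANCC (-1.37), in the list of p53 targets for DNA repair, fell as well. The 3 GLI transcription factors of the Hedgehog pathway fell, GLI1 by 0.61, GLI2 by 0.72 and GLI3 by 0.78 on the log2 scale, while PTCH1 and SMO of that pathway did not pass. They stand in the primary cilium list, of which 21 of 50 rose and 11 fell on the reads (camera adjusted p = 0.556). The chemokines CXCL8 and CXCL2 fell by 1.25 and 1.33 on means of 15.7 reads or fewer, against their senescence-associated list, of which 23 of 33 rose and 3 fell on the reads. The replication-dependent histone genes H4C8 (3.35-fold) and H2BC4 (2.15-fold) rose too.

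Among protein-coding genes outside the lists with a mean of at least 100 reads, the largest rises on the reads included DNAI3, an axonemal dynein intermediate chain (7.71-fold, adjusted p = 1.16e-12, 24.0 to 176.0 reads), the cadherin CDH10 (4.77-fold), the hyaluronan-binding protein CEMIP (4.34-fold), MELTF (4.28-fold) and SELPLG, the P-selectin ligand (3.34-fold). After EGR1, the largest falls among them included the mitotic kinesin KIF18B (-2.04), the transcription factor MYB (-2.01), FBXO43 (-1.99), FAM111B (-1.98) and the glycosylase NEIL3 (-1.94).

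Of 17 copies of 7SL with a symbol, the RNA of the signal recognition particle, 4 fell (RN7SL396P, RN7SL752P, RN7SL4P and RN7SL5P, by between 1.99 and 2.28 on the log2 scale) and 1 rose. The 3 IDs without a symbol among the largest falls are not in this count. Their lengths inferred from the reads were 297 to 300 bases, against 280 for RN7SL396P. They fell by 2.13 to 2.23 on DMSO means of 235 to 823 reads. Their spread was wide inside both groups, as in ENSG00000265150 with 82.2 ± 35.3 RPKM in DMSO and 16.7 ± 6.74 RPKM in Nutlin-3. Whether they are 7SL genes cannot be told from the names used here. 7SL RNAs lack a poly(A) tail, so less carry-over of short RNAs in the Nutlin-3 libraries could lower them. The other 21 short nuclear-encoded RNA genes outside exons of other genes had a median of -0.354 (95% interval -0.584 to -0.0981), which argues against a carry-over that lowers all alike by as much as these 4 copies, while a smaller one, or one of 7SL alone, stays open. The other 8 transcripts of RNA polymerase III outside such exons had a median of -0.399 (-3.81 to 0.446), which leaves a fall of that class open. Both intervals count genes as independent. RNA5SP392 (0.10) and the Y RNA gene ENSG00000206990 (-0.019) have more reads and did not pass, but lie in exons of other genes whose reads may be counted for them.

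AC025423.2, whose exon lies inside exons of MDM2, changed on the reads by 0.0107 less than MDM2 on the log2 scale. The range of 2 standard errors on each side of this difference of -0.0107 was -0.166 to 0.145. It takes the errors of both genes as independent, though both come from the same libraries. So small a difference is what reads of MDM2 counted for the pseudogene would give, and such reads may be the whole of its rise.

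More genes fell than rose by at least 2-fold. The intervals in this paragraph count genes as independent, which genes that move together are not, so they are too narrow. The authors' scaling between libraries as the whole cause is argued against by quantile normalization, with which 79.7% of 271 such genes fell (95% interval 74.4 to 84.3). The pseudocount is argued against by the recovered reads, on which 69.7% of 994 fell (66.8 to 72.6). The 4 cell cycle lists hold 93 of the 212 genes that fell, but without them 68.4% of 174 still fell (60.9 to 75.2), so their members alone do not account for it. Cell cycle genes outside the lists may add to it, which was not tested.

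The 6 libraries can be split 3 against 3 in 10 ways, so the share of splits is never under 0.1 and cannot fall under 0.05. Only 1 split, the real one, gave as many genes changed (6296, highest other 1), as many changed at least 2-fold (267, highest other 1) and as many lists (17, highest other 15). In the other 9 splits, which mix the groups, camera called between 6 and 15 lists, while at most 1 gene passed. Each of these splits has unequal numbers of Nutlin-3 libraries on its sides, so part of the treatment difference remains between the sides. The rest widens the spread within them. Neither count is thus that of a comparison without treatment, and the contrast between lists and genes is built into the splits.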
